A study of Danio rerio with 7 samples.

How the data were processed

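RNA of whole larvae was sequenced from 7 stranded mRNA libraries, per the labels' protocols. FastQC, Trimmomatic, HISAT2 and DESeq2 are named in the submitters' processing notes, without versions or settings. The genome build is GRCz11, per the names of the deposited files, and the program that counted reads is not given in the sources used here. Whether strand was used in counting is not given either, so it is unknown whether reads of overlapping antisense genes were told apart.

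Each library had a gene abundance file in which the authors deposited a TPM value, an FPKM value and a mean read coverage per gene. Per the file headers these columns are coverage, FPKM and TPM, and the coverage was not used in a test. In each deposited file the TPM values of assembled loci summed to 1000000 and those of the reference genes added 739551 to 884988 more. Only the 32520 reference genes were used. A gene listed at several places (62 to 73 genes per library) had its values summed, and no further scaling was applied. The share of TPM held by reference genes differed between libraries, and fold changes in TPM carry that difference.

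The authors also deposited 2 tables of 29567 genes, 1 for high-fat against normal diet and 1 for CACF against normal diet. Per the file headers they hold log2 fold changes with standard errors, a Wald statistic (a score), p-values and adjusted p-values, and a normalized count (signal) per library. The deposited normalized counts were whole multiples of 1 step per library for 100% of values, within a tolerance of 0.001. Whole reads were recovered from those steps. The 3 normal-diet columns were identical in both tables, so 1 set of size factors covers all 7 libraries. Further deposited lists hold the log2 fold change of genes at least 4-fold changed. The counts in these tables are normalized, so the test planned for counts gave way to the one planned for TPM, and the recovered reads were used in alternatives only.

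Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed. Genes with at least 1 TPM in at least 2 of the 7 libraries (18169) were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1). All 7 libraries entered 1 fit with a mean per group and a variance trend, which left 4 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg at 0.05. A fold change is on the scale of TPM plus 1, which understates changes of low genes. The fit was chosen because the 2 groups of 2 libraries give little information on the spread by themselves.

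For gene lists, 39 were fixed and 38 had at least 3 tested members. The list of gonad and yolk genes had 1 tested member and was not tested. camera was run with a preset correlation of 0.01 between genes, and adjusted over the 38 lists. fry and camera with an estimated correlation were run beside it. The pattern of names for ribosomal protein genes also took 12 kinase and other genes. Without them 83 genes were tested, with medians of -0.59 for CACF against normal diet (adjusted p = 1.10e-19), -0.64 for CACF against high-fat diet (adjusted p = 1.50e-20) and 0.03 for high-fat against normal diet (adjusted p = 0.200). Quantile normalization ended the first call (adjusted p = 0.764), reduced the second to a median of -0.17 (adjusted p = 0.0282) and called the third higher (median 0.21, adjusted p = 0.0066). No estimated correlation was run for this shortened list.

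Named genes were the 10 higher and 10 lower genes with the largest change among those past the threshold. They needed a mean of at least 5 TPM in either group, no overlap between the groups' libraries, and a symbol that is not a clone or locus name. With none past it, the 10 smallest p-values were taken. Up to 4 members of each list with the smallest p, and cd36, were added, and the text names some of these.

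The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, FPKM, robust moderation of variances, a fit of the compared groups only, the fish number as a block, each library left out in turn, and DESeq2 1.42.0 on the recovered reads. After the data had been seen, edgeR 4.0.16 on the recovered reads and limma on the deposited normalized counts, for genes with at least 10 in 2 libraries, were added, as were DESeq2 for cd36, the shortened ribosomal list, and the alternatives for the authors' lists. Leaving out a library of a group of 2 leaves 1, which is then assumed to vary like the other groups. Fish 1 occurs only on the normal diet, so the block fits that library exactly. Fold changes with the block therefore equal those without normal-diet fish 1.

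The gene test was tested on simulated reads with 200 changed genes. For CACF against normal diet it recovered 2.99% of 2-fold, 25.4% of 4-fold and 98.5% of 16-fold changes among 17493 genes. For high-fat against normal diet it recovered 1.49%, 29.9% and 98.5% among 17488 genes, and for CACF against high-fat diet 0, 14.9% and 97.0% among 17484 genes. Wrong calls exceeded the 5% that the threshold allows. They made up 19 of 105 calls (18.1%) for high-fat against normal diet, 15 of 99 (15.2%) for CACF against normal diet and 11 of 85 (12.9%) for CACF against high-fat diet.

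In 20 simulated draws with no change at all, the median number of calls was 7, 6 and 6.5 in the same order, with up to 18, 14 and 12. The count of 14 calls for CACF against normal diet thus equals the highest that no change gave. Among genes with a mean of at least 50 reads, a limit chosen after the first draws, the draws gave at most 1, 0 and 1 call. The 14 genes called for CACF against normal diet averaged at least 77.4 reads each, and nr1d1 3318. All simulations used 1 common spread for every gene and library (dispersion 0.199), with no outlying library. In the data the spread differed between genes, and 2 libraries stood apart. The draws thus cannot say how many of the 14 calls are wrong. Of 30 unchanged simulated lists, 0 were called in each comparison. Genes were simulated independently of each other, so this did not test the list calls under correlation between genes. In the data the estimated correlation was 0.84 in the lens list for high-fat against normal diet.

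Depth limits the precision of genes with few reads, and the high-fat diet libraries were the shallowest. Relations between comparisons that share libraries were set against 100 simulated draws.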

Results

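RNA was sequenced from whole larvae of a CD36-overexpressing transgenic zebrafish line at 15 days post fertilization. CD36 is a membrane receptor that takes up long-chain fatty acids. The 7 libraries fell into 3 groups. Larvae on the normal diet (12%) gave 3 libraries, from fish 1, 2 and 4. Larvae on the high-fat diet (24%) gave 2 libraries, from fish 2 and 4. Larvae on the high-fat diet that were also exposed to CACF at 40 µg/ml, overnight after the last meal, gave 2 libraries, from fish 2 and 4. Whether the other groups were held overnight in the same way is not stated in the sources used here. The labels do not explain the abbreviation CACF or give the hour at which any library was sampled, and they do not say whether the fish came from separate clutches, so p-values measure only the spread between these libraries. The series addresses lipid accumulation and liver cancer in this line, with the normal diet as its control.

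Reads per library, recovered from the deposited normalized counts, ran from 12699552 to 22543693. The high-fat diet libraries were the shallowest, with 12699552 reads in fish 2 and 15819634 in fish 4, while the other 5 libraries had at least 18898959. Reads of the mitochondrial genome made up 16.6%, 9.26% and 7.06% of the normal-diet libraries, 13% and 10.3% of the high-fat libraries, and 27.9% and 20.3% of the CACF libraries. Across genes, log2 values of libraries within a group correlated at 0.879 to 0.954 over 5 pairs, and those of libraries from different groups at 0.822 to 0.977 over 16 pairs. No pair agreed within sampling noise. Normal-diet fish 1 and CACF fish 2 stood apart, with median correlations with the other 6 libraries of 0.876 and 0.875, where the other 5 libraries had 0.940 to 0.946.

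The zebrafish cd36 gene was examined first. cd36 (ENSDARG00000032639, GRCz11 chromosome 4, 22658472 to 22671469) had 81.2, 7.06 and 7.49 TPM, the deposited transcript abundance, in normal-diet fish 1, 2 and 4. It had 19.8 and 15.7 TPM in the high-fat libraries and 6.16 and 6.0 TPM in the CACF libraries. None of the 3 comparisons passed in limma, though CACF against high-fat diet did with the fish number as a block (adjusted p = 0.0327). The log2 fold change was 0.07 ± 0.78 (SE) for high-fat against normal diet (adjusted p = 1.0), -1.33 ± 0.78 for CACF against normal diet (adjusted p = 0.493) and -1.40 ± 0.85 for CACF against high-fat diet (adjusted p = 0.548). Normal-diet fish 1 set the first value, which was 1.17 without that library. Without fish 2 or fish 4 of the normal diet it was -0.50 or -0.47, and without fish 2 of the high-fat diet -0.09. The CACF against normal diet value was -0.22 without normal-diet fish 1. On recovered reads the first value was negative, at -1.22 in edgeR and -1.18 in DESeq2, and the second was -2.92 and -2.89. Whether reads of the transgene count toward this gene is not stated in the sources used here.

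**Figure D1:**
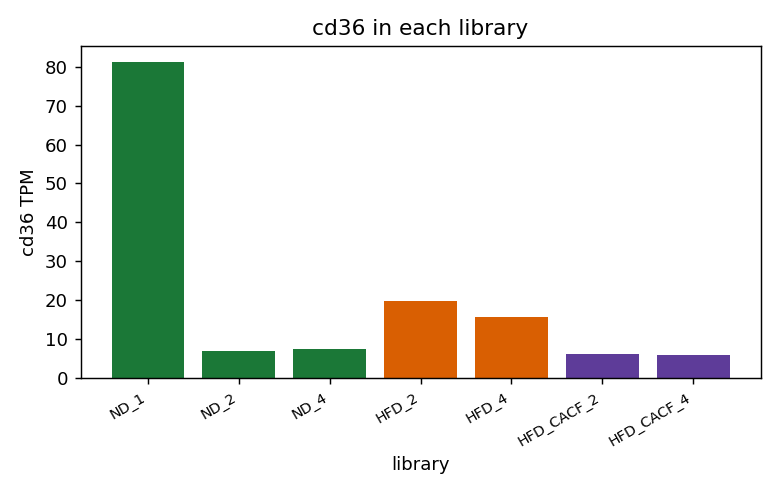
TPM of cd36 in each of the 7 libraries, grouped by diet and treatment, with a bar for each library. Normal-diet fish 1 lies at 81.2 TPM, and the other libraries lie between 6.0 and 19.8.

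The comparison of high-fat with normal diet asks what the diet alone changed in this line. At the level of gene groups, cell division genes were higher on the high-fat diet, with 33 of 36 tested members above the normal-diet mean and a median log2 fold change of 0.52 (camera, adjusted p = 1.31e-10). The glucocorticoid and fasting response was lower (median -0.99, 19 of 21 members, adjusted p = 2.69e-08), as were circadian clock genes (median -0.43, 29 of 34 members, adjusted p = 8.16e-06). For these 3 lists the adjusted p was 0.633 with an estimated correlation. Keratinocyte markers were lower in 28 of 28 members (median -0.57, adjusted p = 9.15e-08, and adjusted p = 0.115 with an estimated correlation). These 4 lists were called with each library left out in turn, but their sizes changed. The glucocorticoid median was -0.45 (adjusted p = 0.0316) and the cell division median 0.28 without normal-diet fish 1, and without normal-diet fish 2 the circadian median was -0.19. None of their members passed singly, either over all genes tested or adjusted over the list alone.

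Examples from these lists did not pass the gene test. rrm2, the small subunit of the enzyme that makes deoxynucleotides, had 30.2 ± 14.2 TPM (SD, n = 2) on the high-fat and 10.4 ± 5.77 TPM (n = 3) on the normal diet (log2 fold change 1.52 ± 0.49, limma adjusted p = 1.0). pcna, the DNA polymerase clamp, had 101 against 49.7 TPM. The muscle atrophy ubiquitin ligase gene fbxo32 had 8.19 ± 4.04 against 28.4 ± 7.49 TPM, and the epidermal keratin gene krt5 had 652 ± 40.3 against 1282 ± 361 TPM. hlfa, a clock output transcription factor gene, had 6.61 against 18 TPM.

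Few lipid gene groups were called. Lipogenesis genes (median 0.01, adjusted p = 0.996), lipid transport genes (0.22, 0.125), cholesterol synthesis genes (0.03, 0.559), bile acid genes (0.21, 0.983), hepatocyte markers (0.14, 0.233) and adipocyte markers (-0.42, 0.147) were not called by camera. Lipogenesis, cholesterol synthesis and bile acid genes stayed uncalled with each library left out, but the others depended on single libraries. Lipid transport genes (median 0.56, adjusted p = 6.03e-15) and hepatocyte markers (0.34, 4.73e-06) were called higher without normal-diet fish 1. Without normal-diet fish 2 their medians turned to -0.35 (adjusted p = 0.1001) and -0.25 (adjusted p = 0.000611, called lower). Both were called higher without high-fat fish 2 as well, and hepatocyte markers also without normal-diet fish 4. Adipocyte markers were called lower without normal-diet fish 4 or high-fat fish 2. With the fish number as a block, which also sets normal-diet fish 1 aside, lipid transport genes and hepatocyte markers had adjusted p-values of 7.66e-16 and 2.53e-07. Fatty acid oxidation genes were called higher (median 0.30, adjusted p = 0.0233, and adjusted p = 0.634 with an estimated correlation), with acads at 15.0 ± 0.182 against 7.92 ± 1.92 TPM. The call ended without fish 2 or 4 of the normal diet (adjusted p = 0.0892 and 0.112) or fish 4 of the high-fat diet (adjusted p = 0.115), and under quantile normalization (adjusted p = 0.0613), and without normal-diet fish 1 the median was 0.105. Lipid storage and lipolysis genes were called lower (median -0.29, adjusted p = 0.0487, and adjusted p = 0.633 with an estimated correlation). That call ended without normal-diet fish 1 (median -0.05, adjusted p = 0.735) or without either high-fat library (adjusted p = 0.0554 and 0.094), and under each scaling alternative. lpl, the lipoprotein lipase gene, had 13.8 ± 1.72 against 34.2 ± 11.8 TPM, and srebf1, a lipogenic transcription factor gene, 1.54 against 2.90 TPM. Liver tumour-associated genes were called lower (median -0.29, adjusted p = 0.0212, and adjusted p = 0.633 with an estimated correlation), but not without normal-diet fish 1 (adjusted p = 0.630) or high-fat fish 2 (adjusted p = 0.0554), under median-of-ratios scaling (adjusted p = 0.102) or on the deposited normalized counts (adjusted p = 0.185).

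Lens genes (median -2.14), immediate early and heat shock genes (-1.40) and inflammation genes (-0.79) were called lower on the high-fat diet (adjusted p = 6.38e-15, 9.13e-13 and 2.38e-05). With an estimated correlation the adjusted p was 0.633 for each. Without normal-diet fish 1 all 3 calls ended, with medians of -0.31, -0.29 and -0.34. That library had a summed TPM of 85011 over the lens list, where the other normal-diet libraries had 1152 and 1781, and of 4403 over the immediate early list, where they had 368 and 316. Photoreceptor markers were not called (adjusted p = 0.900), and their median of -0.15 was opposite in sign to the test.

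No single gene passed for the high-fat against the normal diet in limma (18169 genes tested), edgeR (21309) or DESeq2 (29567). In limma 602 had an unadjusted p under 0.05, 120 higher and 482 lower. That split depended on scaling and on single libraries, with 343 higher and 345 lower under quantile normalization, 383 and 553 under median-of-ratios scaling, 264 and 352 with FPKM, 147 and 177 without high-fat fish 2, and 287 and 976 on the deposited normalized counts. The smallest p belonged to SGMS1, a sphingomyelin synthase gene, with 1.37 against 15.3 ± 3.82 TPM (log2 fold change -2.75 ± 0.40, adjusted p = 0.187), which passed with robust moderation of the variances (adjusted p = 0.0158). Its log2 fold change on the deposited normalized counts was -0.61. The others among the 10 smallest were sept12, with a positive fold change, and dcaf12, actn3b, clint1a, runx1t1, asb10, gas2b, s100w and cbsb, with negative ones, all at an adjusted p of 1.0. gas2b was listed at 0 in both high-fat libraries. On the normalized counts most of these changes shrank to under 50% of their log2 fold change in TPM, with sept12 at 0.27 there, dcaf12 at -0.23, actn3b at -0.60, clint1a at -0.37, asb10 at -0.70 and cbsb at -0.71. runx1t1 had the opposite sign (-2.29 in TPM, 0.21 there), and s100w kept its change (-1.61 in TPM, -1.55 there). In all, camera called 18 of 38 tested lists, 6 higher and 12 lower, against 9 higher and 3 lower without normal-diet fish 1, where 8 of the 18 were called in the same direction. Of the 18, 8 were called with median-of-ratios scaling, 10 with quantile normalization, 8 on the deposited normalized counts and 9 with the fish number as a block.

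Larvae given the high-fat diet with CACF were compared with those on the normal diet, the control named by the series. 14 genes passed in limma, and all 14 were lower with CACF. Clock genes led them. nr1d1 (ENSDARG00000033160, chromosome 3, 23488652 to 23496223), the clock repressor Rev-erb alpha, had 3.22 ± 1.82 TPM (SD, n = 2) with CACF and 93.1 ± 10.6 TPM (n = 3) on the normal diet. This was 23.3-fold lower on the scale of TPM plus 1 (log2 fold change -4.54 ± 0.40, adjusted p = 0.00079). bhlhe41 (chromosome 18, 16125852 to 16130165) and ciarta, 2 further clock repressor genes, were 8.35-fold and 7.20-fold lower (adjusted p = 0.0189 and 0.033). The period genes per1a and per1b were 5.46-fold and 6.65-fold lower (adjusted p = 0.033 and 0.035), and dbpb, a clock output transcription factor gene, 7.09-fold lower (adjusted p = 0.038).

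Over the 34 tested members of the circadian list, 6 fell over all genes tested, and 18 fell and 7 rose adjusted over the list alone. The list was called lower (median -1.25, camera adjusted p = 9.34e-12, and adjusted p = 0.313 with an estimated correlation). Its members moved in both directions. The mixed test of fry, which counts change in any direction, gave an adjusted p of 0.0142, and 3 of the 38 lists passed it in this comparison. The labels give no sampling hour, so whether the groups were matched for time of day is open.

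Genes of cone photoreceptors formed the other part of the calls. The cone arrestin gene arr3b (chromosome 14, 32837914 to 32850768) had 7.04 ± 7.88 against 122.6 ± 50.1 TPM and was 20.2-fold lower (log2 fold change -4.33 ± 0.61, limma adjusted p = 0.0254). guca1c, a guanylate cyclase activator gene, was 9.23-fold lower (adjusted p = 0.0189), rbp4l 6.78-fold lower (adjusted p = 0.0466), and pde6c, the cone phosphodiesterase gene, 6.37-fold lower (adjusted p = 0.040). Of 35 photoreceptor markers, 4 fell over all genes, and 12 fell and 1 rose adjusted over the list alone (median -0.82, camera adjusted p = 2.24e-15, and adjusted p = 0.313 with an estimated correlation). The remaining calls were camkk1b, a calcium-dependent kinase gene (9.20-fold lower, adjusted p = 0.0189), and the microRNA locus dre-mir-29b-1 (14.3-fold lower, adjusted p = 0.033). The latter spans only 47467910 to 47467992 on chromosome 6, so reads of an overlapping transcript could count toward it. The last 2, si:ch211-132b12.7 and si:ch211-161h7.5 (log2 fold changes -4.28 and -3.44), have clone names and were named after their values were seen. arr3b and per1b each have a close paralog, and how reads shared between copies were counted is not given in the sources used here.

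**Figure D2:**
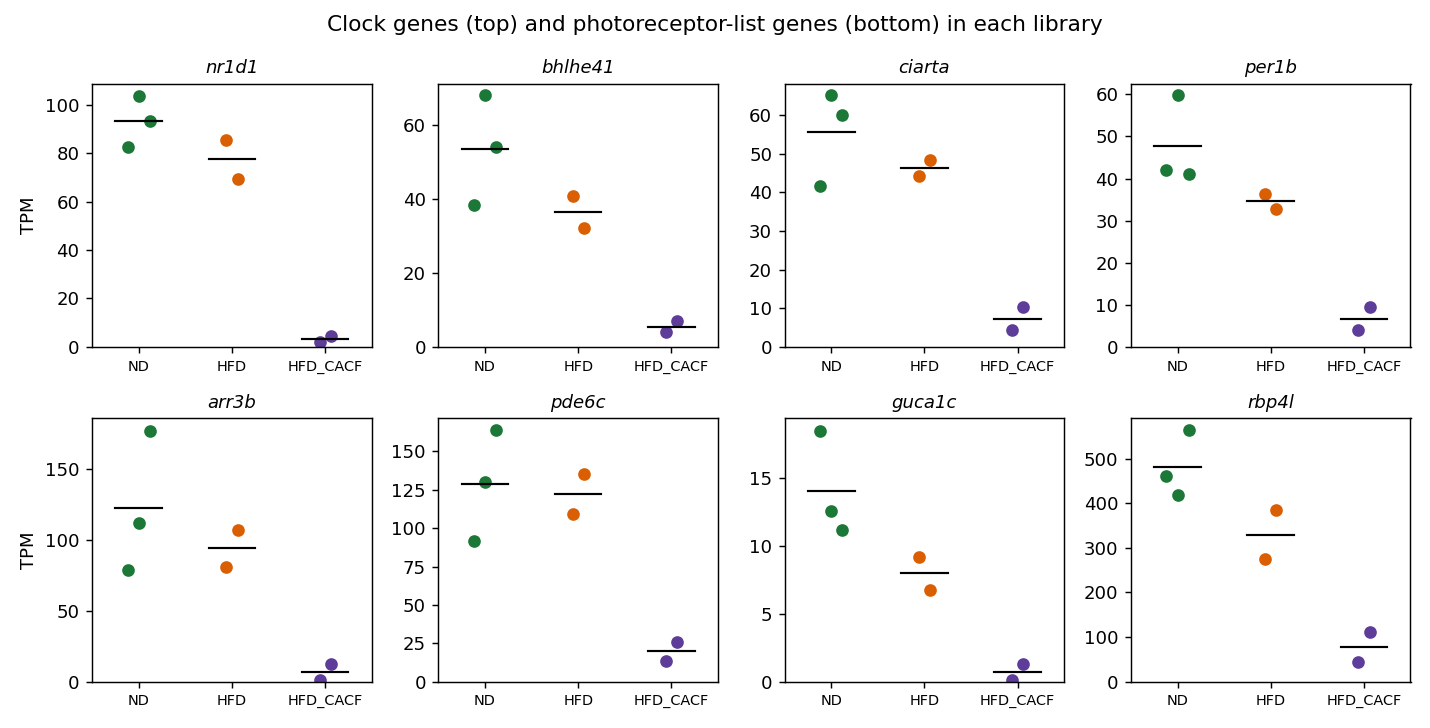
TPM on a linear axis of called clock and cone photoreceptor genes in each library, by group, with 1 point per library. nr1d1 averaged 3.22 TPM in the CACF libraries, 93.1 on the normal diet and 77.5 on the high-fat diet without CACF.

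The 14 calls rested on few libraries. Without CACF fish 2 only nr1d1 passed (adjusted p = 0.021), and without CACF fish 4 126 genes passed, 91 of them lower. Without normal-diet fish 1 or 2 the counts were 5 and 6, which included only 3 and 1 of the 14. Without high-fat fish 2 or 4 they were 62 and 58, with all 14 among them. edgeR called 4 genes, 2 of them among the 14, DESeq2 671, with all 14, and limma on the deposited normalized counts 31, with 12 of the 14. With no filter on low values none of the 14 passed (nr1d1 at adjusted p = 0.054). With the fish number as a block, 155 genes passed, the 14 among them, 40 higher and 115 lower. That fit sets normal-diet fish 1 aside, as leaving it out does.

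Exocrine pancreas genes had the largest median change of the 38 lists in this comparison. All 23 were below the normal-diet mean, 20 of them past the threshold adjusted over the list alone and 0 over all genes in limma (median -2.81, camera adjusted p = 3.24e-24, and adjusted p = 0.313 with an estimated correlation). The trypsin gene prss1 had 15.5 ± 18 against 284 ± 210 TPM (log2 fold change -4.20 ± 0.96, adjusted p = 0.161) and the chymotrypsinogen gene ctrb1 3.08 ± 2.39 against 73.3 ± 54.4 TPM. Summed over the list, the CACF libraries had 15.3 and 157 TPM, the high-fat libraries 343 and 930, and the normal-diet libraries 1607, 177 and 1891. Enterocyte markers were called lower (median -1.35, 23 of 25 members, adjusted p = 6.40e-12), with 3 past the threshold adjusted over the list alone, and so were glucose metabolism genes (median -0.88, adjusted p = 2.59e-07) and xenobiotic response genes (median -0.59, adjusted p = 1.19e-06). For these 3 lists the adjusted p was 0.313 with an estimated correlation. All 3 were called with each library left out, with smaller medians in some cases. They were, without normal-diet fish 1, -0.85 for enterocyte, -0.37 for glucose metabolism (adjusted p = 0.00998) and -0.37 for xenobiotic response genes, and without CACF fish 2 the latter was -0.23. On the deposited normalized counts the enterocyte median was -2.51 and the xenobiotic median -0.99.

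Transcripts of the mitochondrial genome were called higher with CACF. All 13 were above the normal-diet mean and all 13 rose adjusted over the list alone (median 1.44, camera adjusted p = 5.21e-12, and adjusted p = 0.313 with an estimated correlation). mt-atp6 had 50940 ± 18851 against 12795 ± 2406 TPM (limma adjusted p = 0.0782). Cell division genes were called higher (35 of 36, 17 of which rose adjusted over the list alone, median 1.09, adjusted p = 5.51e-13, and adjusted p = 0.356 with an estimated correlation), as were neuron and glia markers (35 of 36, median 0.77, adjusted p = 2.09e-07, and adjusted p = 0.425 with an estimated correlation), whose median was 0.51 on the deposited normalized counts. cdk1, the mitotic kinase gene, had 16.4 ± 6.69 against 5.16 ± 1.4 TPM. Summed over the cell division list, CACF fish 2 and 4 had 749 and 383 TPM. Normal-diet fish 1, 2 and 4 had 140, 295 and 269, and high-fat fish 2 and 4 had 350 and 390. For neuron and glia markers the sums were 7027 and 5636 with CACF and 2464, 6303 and 4016 on the normal diet. Ribosomal protein genes were called lower (85 of 94, median -0.57, adjusted p = 1.92e-16, and adjusted p = 0.363 with an estimated correlation), but their median was -0.26 without CACF fish 2, and quantile normalization turned it to 0.02 (adjusted p = 0.763) and called them higher on the high-fat than on the normal diet (median 0.17, adjusted p = 0.0255). The median of all tested genes was 0.19 in this comparison, 0.16 for CACF against the high-fat diet and -0.03 for the high-fat against the normal diet. Median-of-ratios scaling moved the first 2 medians to 0.01 and -0.03.

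Among lipid genes, fatty acid oxidation genes were called higher (25 of 31, median 0.55, camera adjusted p = 0.00391, and adjusted p = 0.363 with an estimated correlation), and this call held with each library left out, with a median of 0.33 under median-of-ratios scaling. hadhaa and hadhab, which encode subunits of the mitochondrial trifunctional protein, had 11 against 4.16 and 22.9 against 8.24 TPM (limma adjusted p = 0.251 and 0.275). Cholesterol synthesis genes were called higher (23 of 25, median 1.11, adjusted p = 3.10e-07, and adjusted p = 0.363 with an estimated correlation), but the call ended without CACF fish 2 (median 0.23, adjusted p = 0.527). Lipid transport genes were called lower (median -0.40, adjusted p = 0.0131, and adjusted p = 0.381 with an estimated correlation), which ended without normal-diet fish 1 or CACF fish 4 (median 0.10 in both cases), under median-of-ratios scaling, under quantile normalization and on the deposited normalized counts. Hepatocyte markers were called lower (median -0.27, adjusted p = 4.81e-05, and adjusted p = 0.432 with an estimated correlation), but not without normal-diet fish 1 (adjusted p = 0.131), and their median was 0.10 without CACF fish 2 and -0.54 on the deposited normalized counts. Lipogenesis genes (median 0.16, adjusted p = 1.0) and liver tumour-associated genes (median -0.04, adjusted p = 0.108) were not called. fabp6, an ileal bile acid binding protein gene, had 117 ± 136 against 353 ± 106 TPM, and lpl 9.15 ± 3.14 against 34.2 ± 11.8 TPM (adjusted p = 0.168).

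camera called 30 of the 38 lists, 6 higher and 24 lower, 13 of them with each library left out. Without normal-diet fish 1 it called 16, 15 of them among the 30 in the same direction, and the lens call (median -2.12, adjusted p = 3.08e-13, and adjusted p = 0.363 with an estimated correlation) ended, with a median of -0.24. None of the 30 held with an estimated correlation (adjusted p from 0.313 to 0.478) or in fry's test of direction (lowest adjusted p = 0.298).

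**Figure D3:**
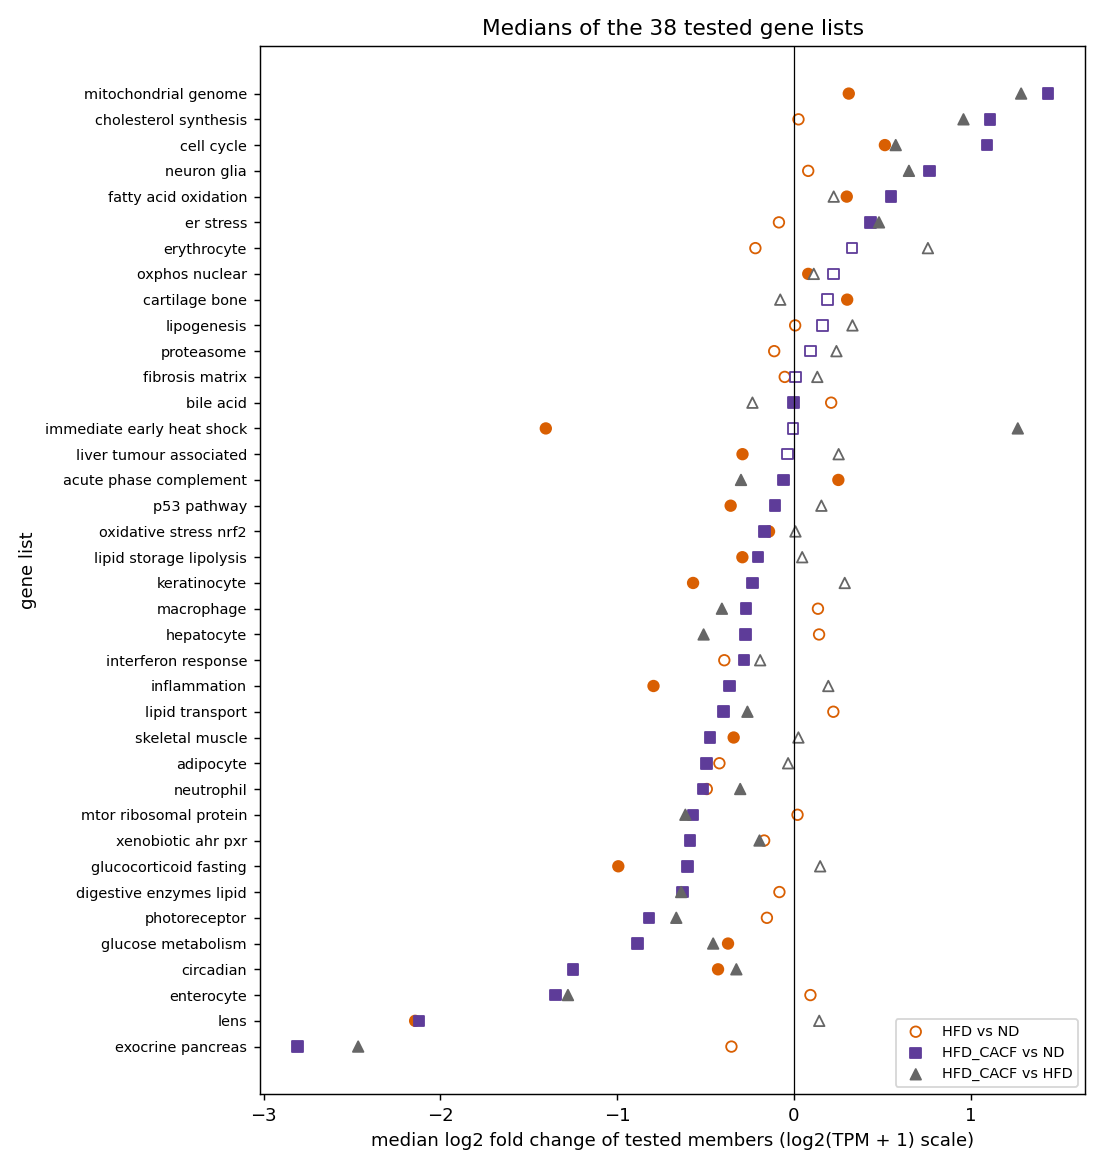
Median log2 fold change of the tested members of each fixed gene list, in each of the 3 comparisons. Filled markers had a camera adjusted p under 0.05 and open markers did not. Exocrine pancreas genes lie at -2.81 and -2.46 in the 2 comparisons with CACF. The ribosomal median turns positive under quantile normalization for CACF against normal diet.

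CACF against the high-fat diet without it compares larvae given the same diet. Since it is not stated how the untreated larvae were held overnight, CACF and overnight handling cannot be told apart. Here nr1d1 passed alone, with 3.22 ± 1.82 TPM (SD, n = 2) against 77.5 ± 11.3 TPM (n = 2), 19.4-fold lower (log2 fold change -4.28 ± 0.44, limma adjusted p = 0.00457). The other clock and cone genes that were lower against the normal diet missed the threshold here. bhlhe41 had 5.52 against 36.5 TPM (adjusted p = 0.0899), arr3b 7.04 against 94.1 TPM (adjusted p = 0.0837) and pde6c 19.7 against 122 TPM (adjusted p = 0.0899). The nr1d1 call ended without CACF fish 2 (adjusted p = 0.0944), in a fit of these 2 groups only (adjusted p = 0.112), in edgeR (adjusted p = 0.0739) and without the filter on low values (adjusted p = 0.122). Without normal-diet fish 4, which changes only the shared estimate of the spread here, 143 genes passed, without CACF fish 4 26 passed, and without normal-diet fish 2 or high-fat fish 2, 2 passed. At an unadjusted p under 0.05 limma gave 2502 genes. edgeR called 0 genes, with 3126 at an unadjusted p under 0.05, and DESeq2 called 965. With the fish number as a block, 940 genes passed, nr1d1 among them, 770 higher and 170 lower.

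All 23 exocrine pancreas genes were lower than on the high-fat diet alone, 15 of them past the threshold adjusted over the list alone (median -2.46, camera adjusted p = 1.90e-18). Enterocyte markers (median -1.28, 24 of 25 lower, adjusted p = 6.22e-11), photoreceptor markers (median -0.66, 32 of 35 lower, adjusted p = 2.02e-15) and hepatocyte markers (median -0.51, 24 of 29 lower, adjusted p = 3.60e-06) were called lower. Mitochondrial genome transcripts were called higher, with 11 of 13 past the threshold adjusted over the list alone (median 1.29, adjusted p = 4.27e-07). For these 5 lists the adjusted p was 0.594 with an estimated correlation. The exocrine median was -1.56 without CACF fish 2, the photoreceptor median -1.03 without CACF fish 4, and the hepatocyte median ran from -0.87 without CACF fish 4 to -0.19 without high-fat fish 4. On the deposited normalized counts the enterocyte, photoreceptor and hepatocyte medians were -2.30, -1.02 and -0.91, and quantile normalization gave a mitochondrial median of 0.60. Circadian genes were called lower (median -0.33, adjusted p = 0.000106, and adjusted p = 0.594 with an estimated correlation), with 7 higher and 12 lower adjusted over the list alone, and a median of -0.59 under quantile normalization. Neuron and glia markers were called higher (median 0.65, adjusted p = 2.33e-05, and adjusted p = 0.652 with an estimated correlation), 8 of them adjusted over the list alone, with medians of 0.41 under median-of-ratios scaling and 0.32 on the deposited normalized counts. vamp2, a synaptic vesicle protein gene, had 55.1 ± 8.98 against 10.8 ± 1.6 TPM (limma adjusted p = 0.0932). Ribosomal protein genes were called lower (82 of 94, median -0.61, adjusted p = 5.60e-17, and adjusted p = 0.594 with an estimated correlation), but not under quantile normalization (median -0.15, adjusted p = 0.052), and their median was -0.29 without CACF fish 2.

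Of the lipid lists, lipid transport genes were called lower than on the high-fat diet alone (22 of 31, median -0.26, camera adjusted p = 0.00101, and adjusted p = 0.594 with an estimated correlation), with fabp1b.1, a liver-type fatty acid binding protein gene, at 4.90 ± 2.76 against 32.5 ± 23.2 TPM (limma adjusted p = 0.306). That call ended under median-of-ratios scaling, quantile normalization and the deposited normalized counts (adjusted p = 0.0551, 0.0531 and 0.0743). Cholesterol synthesis genes were called higher (24 of 25, median 0.96, adjusted p = 2.20e-05, and adjusted p = 0.594 with an estimated correlation), with fdps at 14.8 ± 11 against 2.15 ± 0.117 TPM. The call ended without CACF fish 2 (median 0.17, adjusted p = 0.987). The same library ended the call of immediate early and heat shock genes (median 1.27, adjusted p = 0.000332, and adjusted p = 0.733 with an estimated correlation), whose median was 0.50 without it, and of endoplasmic reticulum stress genes (median 0.48, adjusted p = 0.00619, and adjusted p = 0.594 with an estimated correlation), whose median was 0.23 without it. The latter call also ended on the deposited normalized counts (adjusted p = 0.0754), and its median was 0.26 under median-of-ratios scaling. Lipogenesis (0.33, adjusted p = 0.924), lipid storage and lipolysis (0.05, 0.587), fatty acid oxidation (0.23, 0.338) and liver tumour-associated genes (0.25, 0.804) were not called. Within the uncalled fatty acid oxidation list, ppargc1a, a regulator of mitochondrial biogenesis, had 3.11 ± 0.512 against 0.401 ± 0.253 TPM (adjusted p = 0.112), and on the normal diet 2.21 ± 1.22 TPM. pdk4, which restrains glucose oxidation, had 3.24 against 0.518 TPM (adjusted p = 0.12), and srebf1 3.94 against 1.54 TPM (adjusted p = 0.247). camera called 19 of 38 lists, 6 higher and 13 lower, or 6 higher and 8 lower under median-of-ratios scaling. With each library left out, 12 of the 19 were called.

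Because comparisons shared libraries, their relation was set against 100 simulated draws of unchanged groups. High-fat against normal diet and CACF against normal diet shared 0 called genes, since limma called none in the first (edgeR and DESeq2 called none there either, and 602 genes had an unadjusted p under 0.05). The covariance of their log2 fold changes over 18169 genes was 0.0767, below the simulated 0.0933, and 58.7% of genes had the same sign, below the simulated 63.2%. High-fat against normal diet and CACF against high-fat diet had a covariance of -0.120, where the simulated value was -0.141, and 62.1% of genes had opposite signs, where simulation gave 68.4%. Without normal-diet fish 1 the covariances were 0.0311 (simulated 0.101) and -0.113 (simulated -0.100). On the deposited normalized counts they were 0.0907 (simulated 0.198) and -0.412 (simulated -0.297), so the second pair lay on either side of simulation depending on the setting. The draws took libraries of different groups as independent. In the data, differences between fish 2 and fish 4 within a group correlated at 0.475, 0.290 and 0.194 between groups. The differences from simulation are therefore not interpreted. Since no gene was called for the diet, no called gene could be followed with CACF.

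In the authors' deposited tables, lists of genes at least 4-fold changed held 732 higher and 2178 lower genes for high-fat against normal diet, and 949 higher and 1960 lower genes for CACF against normal diet. They held every gene with an absolute log2 fold change of 2 or more, up to p-values of 0.815 and 0.814, and their median total over 5 libraries was 11 and 10 reads. Of these genes, 58 (1.99%) and 189 (6.50%) had an adjusted p under 0.05 in the authors' deposited tables. Over the whole lists 0 and 14 genes passed here in the same direction in limma. At any fold change the authors' deposited tables had 14 higher and 46 lower genes with an adjusted p under 0.05 for high-fat against normal diet, and 53 higher and 225 lower for CACF against normal diet. Only 20 and 201 of these were among the genes tested here, so the others could not pass. All 20 and all 201 had the same direction here, and 0 and 11 passed. nr1d1 had a log2 fold change of -5.05 and an adjusted p of 5.30e-06 in the authors' deposited table of CACF against normal diet.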

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

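The tests with edgeR and on the deposited normalized counts, DESeq2 for cd36, and the alternatives for the authors' lists were chosen after the data had been seen. The cause of each difference below was not tested. With 2 or 3 libraries per group, the counts of called genes changed with most settings. High-fat against normal diet gave 0 genes in every setting except robust moderation of variances, with 1. For CACF against normal diet (14 genes), the count was 2 with no filter on low values, 39 with a filter of 5 TPM, 8 with quantile normalization, 3 with FPKM, 64 with robust moderation and 60 in a fit of these 2 groups. It was 31 on the deposited normalized counts, 4 in edgeR and 671 in DESeq2. With single libraries left out it ran from 1 to 126. For CACF against high-fat diet (1 gene), it was 5 with a pseudocount of 0.1, 0 with no filter, 4 with a filter of 5 TPM, 273 with robust moderation, 0 in a fit of these 2 groups, 3 on the normalized counts, 0 in edgeR and 965 in DESeq2, and 0 to 143 with libraries left out. In limma 2502 genes had an unadjusted p under 0.05 there, and in edgeR 3126.

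The fish numbers were tried as a replicate block. Differences between fish 2 and fish 4 within a group correlated across genes at 0.475, 0.290 and 0.194 between the groups. The groups share only 2 numbers, so the numbers are not taken to pair the libraries. Fish 1 occurs only on the normal diet, so the block fits that library exactly. Fold changes with the block therefore equal those without normal-diet fish 1. With the block 155 genes were called for CACF against normal diet, 940 for CACF against high-fat diet, and 98 of the authors' 4-fold genes for CACF against normal diet. It gave 19 called lists for CACF against normal diet, 18 of them among the 30 called without it, and 13 for high-fat against normal diet, 9 of them among the 18. cd36 for CACF against high-fat diet had -1.40 with an adjusted p of 0.0327, where its adjusted p ran from 0.0327 to 1 over the alternatives.

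Of the 18 lists called for high-fat against normal diet, 9 were called in the same direction with a pseudocount of 0.1, 8 with median-of-ratios scaling, 10 with quantile normalization (of 11 called there) and 8 on the normalized counts, and 8 to 17 when single libraries were left out. The total of called lists, new ones included, was then 12 to 22. Of the 30 lists for CACF against normal diet, 15 to 30 were called in the same direction with libraries left out, with 15 without normal-diet fish 1, and the total was 16 to 31. Of the 19 lists for CACF against high-fat diet, 12 were called on the normalized counts and 14 to 19 with libraries left out, and the total there was 16 to 22. With an estimated correlation 0 lists were called in each comparison.

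cd36 for high-fat against normal diet (0.07) was -0.053 with a pseudocount of 5, -1.22 in edgeR and -1.18 in DESeq2, and -0.50 to 1.17 with libraries left out. Its values for CACF against normal diet ran from -1.90 to -0.22 with libraries left out and from -2.92 to -0.22 over all alternatives, and against high-fat diet from -1.56 to -1.24 and from -1.71 to -1.03, all with the same sign. runx1t1 for high-fat against normal diet was 0.21 on the normalized counts, 0.11 in edgeR and 0.14 in DESeq2. Of the authors' 4-fold genes for CACF against normal diet, 14 passed, and 9 with a pseudocount of 5, 2 with no filter, 37 with a filter of 5 TPM, 8 with quantile normalization, 3 with FPKM, 54 with robust moderation, 52 in a fit of these 2 groups, 26 on the normalized counts, 4 in edgeR, 274 in DESeq2 and 1 to 87 with libraries left out. With robust moderation the 1 gene called for the diet, SGMS1, had an opposite sign in TPM for CACF against high-fat diet. In the authors' deposited tables it was -0.71 for high-fat against normal diet and -1.61 for CACF against normal diet, so this reversal was not seen in counts. Over the other named genes, 1443 values kept their direction and side of the threshold, 95 came past it and 89 fell short of it.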

Other observations

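All tests of explanations below were chosen after the result was seen. Several gene groups not described above were also measured with CACF against the normal diet. Skeletal muscle genes were called lower (30 of 39, median -0.47, camera adjusted p = 6.12e-05, and adjusted p = 0.472 with an estimated correlation), as were keratinocyte markers (20 of 28, median -0.23, adjusted p = 0.000246, and adjusted p = 0.313 with an estimated correlation). Quantile normalization gave the muscle list a median of -0.18, and the keratinocyte median was -0.45 under median-of-ratios scaling and -0.64 on the deposited normalized counts. The keratin gene krt92 had 15.8 ± 12.3 (SD, n = 2) against 81.3 ± 3.03 TPM (n = 3, limma adjusted p = 0.128). Neutrophil markers were called lower (7 of 8, median -0.51, adjusted p = 0.00216, and adjusted p = 0.313 with an estimated correlation), but not without normal-diet fish 1 (adjusted p = 0.128), and their median was -0.23 without CACF fish 2 and -0.92 without CACF fish 4. Macrophage markers were called lower (11 of 15, median -0.27, adjusted p = 0.0191, and adjusted p = 0.473 with an estimated correlation), but not without normal-diet fish 1 or 4 or CACF fish 2 (adjusted p = 0.0855, 0.227 and 0.925, with a median of 0.20 without the last) or under median-of-ratios scaling (adjusted p = 0.0593). Fibrosis and matrix genes (median 0.01, adjusted p = 0.269), proteasome genes (0.09, 0.716), erythrocyte genes (0.33, 0.723), nuclear oxidative phosphorylation genes (0.23, 0.547) and cartilage and bone genes (0.19, 0.867) were not called.

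Clock and cone genes were lower with CACF than on the normal diet. Fewer photoreceptor cells would lower the opsins too. Their median log2 fold change was 0.26 over 7 genes (quartiles -0.22 to 0.78, 5 higher and 2 lower). It was -0.27 for CACF against high-fat diet (3 higher and 4 lower). Normal-diet fish 1 had low opsin values, for example 47.5 TPM of opn1sw2 beside 144 and 150 in fish 2 and 4. The 4 called photoreceptor genes had a median of -2.98, but were picked as called, and all 35 markers had -0.82. The opsins argue against a loss as large as in those 4 genes, and a smaller loss stays open. Scaling between libraries moves all genes together, and it is argued against by the median of all tested genes, which was 0.19. The called genes had a median of -3.29 under median-of-ratios scaling. That value adds nothing, since this scaling moved the median of all genes only to 0.01. A difference in clock phase between the groups goes with the 6 positive-limb clock genes, whose median was 1.13 with 6 of 6 higher. None of these was among the calls. Negative-limb and output genes had a median of -1.91 with 16 of 16 lower. That list holds the 6 called clock genes, so its fall, also at equal diet, in part repeats the calls. The 14 called genes were also compared at equal diet. For CACF against high-fat diet their median was -2.62 (quartiles -3.06 to -2.45, 14 of 14 lower). For high-fat against normal diet it was -0.41 (quartiles -0.56 to -0.28). These genes were chosen as called against the normal diet, on the same CACF libraries, which favours low CACF values here too. The high-fat against normal diet value uses no CACF library, and choosing genes high on the normal diet would lower it. It was -0.41, where the median for CACF against normal diet was -3.13. For these 14 genes this argues against the difference in diet as the whole cause. The positive-limb median was 1.22 (6 of 6 higher) at equal diet and the negative-limb and output median -1.68 (15 of 16 lower), against -0.22 and -0.46 for high-fat against normal diet. Whether time of sampling, overnight handling or CACF underlies such a difference stays open. The labels give no sampling hour and do not say how untreated larvae were held overnight.

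Crystallin genes were 59.6-fold higher in normal-diet fish 1 than in the mean of the other normal-diet libraries, with summed TPM of 109511, 1375 and 2303 over 50 genes in fish 1, 2 and 4. TPM is already scaled for depth, so the reads of fish 1, 1.13 times the others' mean, test nothing further. More eye tissue is argued against. The photoreceptor list had a median log2 difference of -0.81 (quartiles -1.26 to -0.41) in fish 1, where the lens list had 5.90. No other biological explanation was tested, since the pattern lies within 1 group, and more lens alone stays open.

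Of the genes with an unadjusted p under 0.05 for high-fat against normal diet, 482 were lower in TPM and 120 higher. Under quantile normalization the split was 345 lower and 343 higher, under median-of-ratios scaling 553 and 383, and with FPKM 352 and 264, so scaling between libraries stays open as a cause of the imbalance. On the deposited normalized counts it was 976 and 287. The hypothesis that TPM fell without a fall in reads was tested on the 264 lower genes with a log2 fold change of -1 or less, whose TPM median was -1.22. It is argued against for the set as a whole, since their median on the deposited normalized counts was -1.57 (quartiles -2.01 to -1.21), and 223 of them (84.5%) were lower there by at least 1. It is not excluded for single genes, as 5 had the opposite sign there, and SGMS1, dcaf12, actn3b and clint1a, among the 10 smallest p-values, had -0.61, -0.23, -0.60 and -0.37. The lower depth of the high-fat libraries cannot be told apart from the diet, because the deepest of them had 0.837 times the reads of the shallowest other library. An effect of the diet stays open and untested.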
